A study of Mus musculus with 76 samples.

How the data were processed

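RNA from the livers of mouse embryos (strain C57BL/6NJ, embryonic day 14.5) was sequenced in 76 libraries, per the labels, as stranded total RNA after depletion of ribosomal RNA. The libraries come from a DIS3 line and an EXOSC10 line, each with knockout (KO) and wild-type (WT) embryos. In each line, total fetal liver and fractions named S0, S1, S2, S3 and S4+S5 after sorting on CD71 and Ter119 were profiled, per the labels. The labels name 4 replicates per genotype of total liver and 3 per genotype of each sorted fraction. They do not say whether replicates come from separate animals, so replicates may be technical, and the p-values measure only the spread between samples.

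The deposited values are raw counts of reads per Ensembl gene, 1 file per library with 49585 genes, and they were not normalised, as the whole numbers and unequal totals in the files show. Per the submitters' processing notes, HISAT2 2.1.0, Subread (no version stated), featureCounts 1.6.4, R 3.5.1 and DESeq2 1.20.0 were used with genome build GRCm38. The notes name neither the annotation release nor the strand setting of the counting, so reads of overlapping genes on opposite strands may not be separated. Gene symbols, biotypes and coordinates were taken from GENCODE release M21 on GRCm38, in which 49326 of the 49585 identifiers were found; the other 259 held 0.0483% of all counts and stayed in the tests under their identifiers. Libraries held 4.66 M to 30.41 M counts (median 12.71 M). The highest share belonged to the predicted genes Gm26917 and Gm42418, 5.264% to 61.418% of a library's counts, uneven in groups such as DIS3 KO S2 (35.2% to 61.4%).

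Replicates were first compared with each other by a chi-square statistic on genes with at least 20 counts over both libraries. In 24 of the 84 within-group pairs the statistic per degree of freedom lay between 1.077 and 1.327, close to what repeated sequencing of 1 library gives, whereas the other pairs lay between 2.798 and 20.293. Pairs under 1.5 were summed and counted as 1 sample, which left 52 samples. Each sorted group then had 2 samples, made of replicate 2 and the sum of replicates 1 and 3 in the DIS3 line, and of replicate 1 and the sum of replicates 2 and 3 in the EXOSC10 line. Total liver had 4 WT and 2 KO samples in the DIS3 line (KO replicates 1 with 3 and 2 with 4) and 3 of each in the EXOSC10 line (WT replicates 3 with 4, KO replicates 2 with 4).

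Before the data were examined, the tests, the gene lists, the rule for named genes and the other settings to be tried were fixed; the summing of near-identical libraries was decided afterwards. KO was compared with WT of the same line and population with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM scaling and the filterByExpr filter, with only the groups compared in the fit and no replicate block. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is from this test. Levels are CPM (counts scaled to a common library size), computed from the deposited counts with TMM-scaled library sizes within each comparison. Their means are given without SD. Differences between the lines in the KO effect, and between the sorted populations within a line, were tested as interaction terms in the same way, and WT populations were compared with an F test in the same framework.

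Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with an inter-gene correlation preset to 0.01, each list of at least 5 measured members against all other tested genes. Benjamini-Hochberg adjustment ran over all 364 list tests. Camera with an estimated correlation and fry were run beside it. The lists were exosome and cofactors, heme and iron, red cell membrane and cytoskeleton, erythroid transcription factors, terminal maturation and organelle clearance, stem and progenitor, macrophage, granulocyte, megakaryocyte, mast cell and basophil, lymphoid, hepatocyte, endothelial, stellate and mesenchymal, p53 targets, interferon-stimulated, integrated stress response, S phase, G2 and mitosis, ribosome biogenesis, DNA damage response and repair, other stable small RNAs, snoRNA host genes, known nuclear lncRNAs, replication-dependent histones, snoRNA and scaRNA, spliceosomal snRNA, ribosomal proteins, the mitochondrial genome, long non-coding RNA (7763 genes by biotype), divergent lncRNA (1169 genes whose start lies within 1000 bases of that of a protein-coding gene on the opposite strand) and microRNA host or precursor. Adult and embryonic globins were also fixed as lists but had too few measured members for a test. Some genes stand in more than 1 list, such as Sesn2, Pvt1 and Tal1.

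A maturation index was computed per sample as the mean log2 CPM of 100 late genes minus that of 100 early genes. Late and early genes were those with the highest and lowest S4+S5 over S0 ratio in the WT samples of the other line, so that no sample under test chose its genes. KO and WT indices were compared by an exact two-sided permutation test.

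The genes named follow the rule fixed in advance. It takes the targeted gene in every sample. From each total liver comparison it takes the 10 genes per direction, and from each sorted comparison the 5 per direction, with the largest fold change among those that passed the test, had an average log2 CPM of at least 1 and showed no overlap between KO and WT samples; pseudogenes were left out, and predicted genes and genes without a symbol took at most 3 of 10 (2 of 5) places. From each list it takes up to 4 members with the smallest p, and from the interaction tests the genes with the smallest p (5 per direction between lines, 10 across populations). In the WT series it takes up to 4 members per cell type list with the highest mean CPM. The text names these or a part of them; other genes are said to have been chosen after their values were seen. Where every sample of a group had 0 counts, the fold is a lower bound computed against 3 counts over that group. Intervals and bounds of this kind cover counting error only.

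The other settings fixed beforehand were DESeq2 size factors, TMM scaling without globin, mitochondrial, small RNA and histone genes, no expression filter, a stricter filter of 1 CPM, the DESeq2 1.42.0 Wald test, the replicate number as a block, a single fit of all sorted samples of a line, leaving out each sample in turn, genes with an average log2 CPM of at least 3 for the correlations, and 300 genes per direction, no globin genes or genes of the same line for the index. Settings chosen after seeing the data were every library as its own sample, leaving out Gm26917 and Gm42418, leaving out chromosomes X and Y in the DIS3 line, keeping only the WT sample without Y-linked counts in DIS3 total liver, exchanged replicate numbers in the block, and leaving out the first or second WT or KO sample in the list tests. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

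On simulated counts with 200 genes changed 2-fold or 4-fold, the procedure recovered 76% and 91% in DIS3 total liver, with 11.6% of calls false. In EXOSC10 total liver it recovered 83% and 98% with 7.2% false, in DIS3 S0 67% and 81% with 5.7% false, in DIS3 S4+S5 55% and 82% with 5.5% false, and in EXOSC10 S2 66% and 93% with 9.7% false. The test between lines recovered 61% and 82% in total liver (7.7% false) and 29% and 63% in S0 (8.9% false). The WT population test recovered 56% and 70% in the DIS3 line (10.6% false) and 51% and 81% in the EXOSC10 line (23.3% false). In simulated EXOSC10 total liver and DIS3 S0 only the list of changed genes was called. The KO comparisons and the WT series called at least 2118 genes each, so the shares above need not hold for them.

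Splicing, transcript ends and reads outside annotated genes could not be examined from gene counts. The KO deletions are not described in the labels, so counts of the targeted genes cover whole genes, including any part that was not deleted.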

Results

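DIS3 and EXOSC10 are the ribonucleases of the RNA exosome, the complex that trims and degrades many nuclear RNAs. The series was set up to ask which genes and non-coding RNAs depend on each of them while red blood cells mature. It holds 76 libraries, counted here as 52 samples, of total fetal liver and sorted fractions S0 to S4+S5. Total liver libraries held 4.66 M to 30.41 M counts (median 20.92 M) and sorted ones 5.41 M to 19.88 M (median 12.02 M), or 3.24 M to 16.06 M without Gm26917 and Gm42418. Below, levels are mean CPM in WT and then in KO, log2 values are KO over WT, and ± after a log2 value is its standard error. A list is given with the median log2 value of its measured members and its adjusted p, and then with the adjusted p under an estimated correlation. With the estimated correlation none of the 364 list tests reached an adjusted p under 0.05 (lowest 0.128), although 37 had an unadjusted p under 0.05. In no called list did the median, the mean and the test differ in sign.

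The targeted genes kept a large part of their counts in KO. Dis3 (chromosome 14, minus strand, 99075206 to 99099770) stood in DIS3 total liver at 29.8, 30.3, 49.9 and 43 CPM in WT and at 32.4 and 31.7 CPM in KO, which was not called (log2 -0.25 ± 0.17, adjusted p = 0.245). With only the WT sample without Y-linked counts kept, the change was called with log2 -0.66, with the spread taken from the 2 KO samples alone. Without that sample it was log2 -0.053 and not called. In the sorted cells of that line Dis3 fell from 52.4 to 26.9 CPM in S0 (log2 -0.95 ± 0.11, adjusted p = 0.000106) and from 65.9 to 41.6 CPM in S1 (log2 -0.66 ± 0.07, adjusted p = 2.18e-05). It fell from 50.3 to 30.1 CPM in S2 (log2 -0.73 ± 0.15, adjusted p = 0.0127; not called without WT replicate 1-3, log2 -0.68). In S3 it fell from 29.8 to 24.1 CPM (log2 -0.31 ± 0.09, adjusted p = 0.0217). This call was lost without WT replicate 2 (log2 -0.30) or KO replicate 1-3 (log2 -0.26), with the DESeq2 Wald test (log2 -0.31) and in a single fit of the sorted samples (log2 -0.41). In S4+S5 Dis3 stood at 8.92 and 7.14 CPM in WT and 3.48 and 7.13 CPM in KO (log2 -0.68 ± 0.36, adjusted p = 0.134), and was called without KO replicate 2 (log2 -1.225), in a single fit of the sorted samples (log2 -0.99) and with every library as its own sample (log2 -0.85). Without KO replicate 1-3 it was log2 -0.18 and not called. Exosc10 (chromosome 4, plus strand, 148558429 to 148582401) stood in EXOSC10 total liver at 68.4, 61.5 and 43.3 CPM in WT and 38.5, 37.2 and 37.5 CPM in KO (log2 -0.60 ± 0.13, adjusted p = 0.00158). It fell in S0 from 62.6 to 16.9 CPM (log2 -1.90 ± 0.14, adjusted p = 0.000136), in S1 from 68.6 to 27.7 CPM (log2 -1.31 ± 0.10, adjusted p = 8.88e-10) and in S2 from 70.6 to 36.1 CPM (log2 -0.97 ± 0.10, adjusted p = 0.000384). In S3 it fell from 40.1 to 29.4 CPM (log2 -0.44 ± 0.08, adjusted p = 0.00151). The fall in S4+S5, from 18.7 to 10.9 CPM (log2 -0.78 ± 0.17, adjusted p = 0.0352), was not called without WT replicate 1 (log2 -0.77) or WT replicate 2-3 (log2 -0.85), nor with the DESeq2 Wald test (log2 -0.79).

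**Figure D1:**
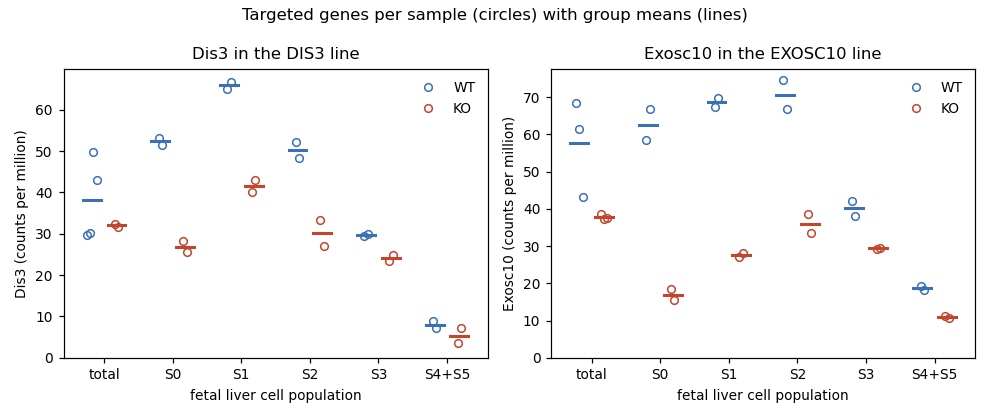
Dis3 and Exosc10 per sample in their own line; Dis3 fell from 52.4 to 26.9 CPM in S0 of the DIS3 line and Exosc10 from 62.6 to 16.9 CPM in S0 of the EXOSC10 line.

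In WT cells the sorted fractions followed the known order of erythroid maturation. The band 3 gene Slc4a1 stood at 11.5, 117.8, 1285, 21190 and 44950 CPM from S0 to S4+S5 in the DIS3 line, and the heme gene Alas2 at 1.57, 12.7, 76.1, 3028 and 19050 CPM. Adult Hbb-bs went from 0.745 CPM in S0 to 6118 CPM in S4+S5 and embryonic Hbb-y from 0.112 to 1858 CPM, below Slc4a1 for reasons not tested. The transferrin receptor gene Tfrc was highest in S3 of the DIS3 line (4937 CPM, against 151.3 CPM in S0 and 2852 CPM in S4+S5) and in S4+S5 of the EXOSC10 line (5449 CPM, against 4834 CPM in S3). The progenitor genes Myb (429.3 CPM in S0, 14.9 CPM in S3) and Kit (273.7 and 6.60 CPM) fell up to S3 and were higher again in S4+S5 (76.9 and 53.3 CPM). So they were in the EXOSC10 line (83.8 and 54.4 CPM in S4+S5, 15.2 and 10.2 CPM in S3). S0 and S4+S5 also held RNA of other cells: macrophage Csf1r stood at 108.8 CPM in S0, 4.16 CPM in S1 and 238.9 CPM in S4+S5, and the B cell gene Rag1 at 45.6, 1.37 and 7.25 CPM. In the EXOSC10 line Slc4a1 went from 24.1 to 51860 CPM, Alas2 from 4.58 to 13960 CPM and Hbb-bs from 0.734 to 1643 CPM. Between the 5 populations, 13960 of 15730 tested genes differed in the DIS3 line and 14098 of 16323 in the EXOSC10 line.

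**Figure D2:**
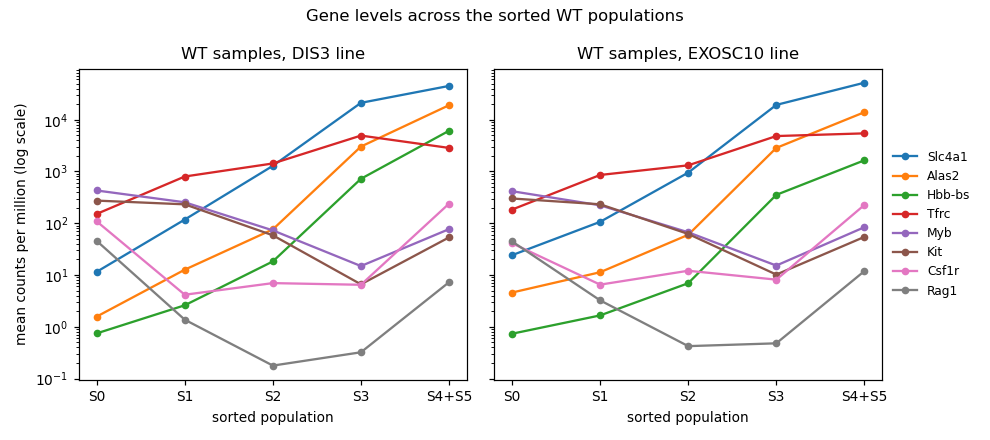
Levels of 8 marker genes over the sorted WT populations; Slc4a1 went from 11.5 to 44950 CPM in the DIS3 line and from 24.1 to 51860 CPM in the EXOSC10 line.

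In KO total liver of the DIS3 line, p53 targets and hepatocyte genes rose, and genes of red cells, of cell division and of B cells fell. Cdkn1a, the p53 target that halts the cell cycle, rose from 5.61 to 132 CPM (log2 4.58 ± 0.11, adjusted p = 1.3e-12). Eda2r, a death receptor of the same pathway, rose from 0.39 to 11.3 CPM (log2 4.73 ± 0.21), and Hamp, the liver hormone that limits iron export, from 5.44 to 107 CPM (log2 4.26 ± 0.15). Ighm, the heavy chain of IgM, fell from 16.8 to 0.339 CPM (log2 -5.62 ± 0.21). Over 4 WT and 2 KO samples, 17553 genes were tested. Of these 4659 rose and 4240 fell, 1850 and 1106 of them by at least 2-fold. Among 30 p53 targets, 23 rose and 3 fell (median 0.95, adjusted p = 1.78e-06, or 0.237 with an estimated correlation), with the same counts adjusted over the list alone; Zmat3 rose from 9.36 to 63.5 CPM (log2 2.81 ± 0.11). All 18 hepatocyte genes rose, also over the list alone (median 1.09, adjusted p = 1.21e-09, or 0.319 with an estimated correlation), such as Hnf4a (109.6 to 225.2 CPM, log2 1.04 ± 0.10). Of 12 endothelial genes 10 rose (median 0.37, adjusted p = 0.00384, or 0.536 with an estimated correlation), Flt4 from 38.5 to 52.3 CPM. Of 12 stellate and mesenchymal genes 8 rose (median 0.66, adjusted p = 0.0127, or 0.571 with an estimated correlation), such as Dcn (37.2 to 67.2 CPM, log2 0.85 ± 0.12). The Y-linked genes Ddx3y (34.1 to 0.0653 CPM) and Uty (28.3 to 0.131 CPM) fell as well. Ddx3y stood at 42.6 to 50.3 CPM in 3 WT samples and at 0.0791 CPM in the other. With only that other WT sample kept, and the spread taken from the 2 KO samples, 4992 genes were called.

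Red cell genes fell together in DIS3 total liver. All 21 red cell membrane genes fell (median -0.97, adjusted p = 8.13e-11, or 0.557 with an estimated correlation), led by the water channel gene Aqp1 (329.7 to 62.0 CPM, log2 -2.41 ± 0.12). Of 20 heme and iron genes 18 fell and 1 rose, and 19 fell over the list alone (median -0.88, adjusted p = 5.53e-07, or 0.571 with an estimated correlation), such as Uros (219.9 to 99.3 CPM). All 16 genes of the erythroid transcription factor list fell (median -1.0, adjusted p = 1.78e-08, or 0.507 with an estimated correlation), among them Zbtb7a (301.6 to 138.0 CPM). So did 17 of 18 terminal maturation genes (median -0.79, adjusted p = 2.38e-06, or 0.567 with an estimated correlation), among them Trim58 (54.2 to 22.7 CPM). Every gene of the S phase list (20, median -0.83, adjusted p = 2.58e-08, or 0.567 with an estimated correlation) and of the G2 and mitosis list (20, median -0.80, adjusted p = 1.02e-09, or 0.507 with an estimated correlation) fell, for example Cdc6 (154.0 to 71.2 CPM) and Ccnb2 (192.1 to 89.4 CPM). Of 61 histone genes 57 fell, 59 over the list alone (median -1.68, adjusted p = 9.21e-22, or 0.538 with an estimated correlation), Hist1h3i from 269.9 to 72.3 CPM. DNA repair genes fell in 16 cases of 19 (median -0.64, adjusted p = 3.88e-06, or 0.309 with an estimated correlation), Fanca from 60.4 to 29.4 CPM. All 10 lymphoid genes fell (median -5.25, adjusted p = 5.33e-10, or 0.319 with an estimated correlation): Rag1 stood at 9.66 and 0.0211 CPM, Pax5 at 7.20 and 0.0112 CPM, and Cd79b fell from 6.30 to 0.630 CPM (log2 -3.33 ± 0.23). Macrophage genes fell in 13 of 18 cases and rose in 2 (median -1.37, adjusted p = 2.7e-05, or 0.538 with an estimated correlation), Csf1r from 115.0 to 19.3 CPM (log2 -2.58 ± 0.11). Granulocyte genes were not called as a list (6 of 12 fell and 2 rose, adjusted p = 0.145).

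RNA classes moved in DIS3 total liver too. Of 390 lncRNAs that start back to back with a coding gene, a kind of transcript the exosome is known to degrade, 184 rose and 24 fell, and 187 and 25 over the list alone (median 0.71, adjusted p = 7.75e-07, or 0.128 with an estimated correlation), such as Gm4673 (4.93 to 18.6 CPM, log2 1.93 ± 0.14). Of all 1065 lncRNAs 443 rose and 95 fell (median 0.61, adjusted p = 3.23e-05, or 0.237 with an estimated correlation); 2900052L18Rik went from 1.203 to 11.5 CPM (log2 3.20 ± 0.18). Host genes of snoRNAs rose in 8 of 15 cases (median 0.51, adjusted p = 0.0068, or 0.571 with an estimated correlation), Snhg20 from 6.03 to 13.9 CPM. Of 52 microRNA hosts and precursors 29 rose and 3 fell (median 1.08, adjusted p = 0.0031, or 0.571 with an estimated correlation), such as Mir451a (1.49 to 8.65 CPM), a microRNA of red cells. Genes of the mitochondrial genome rose in 15 of 18 cases, 16 over the list alone (median 1.02, adjusted p = 2.83e-05, or 0.536 with an estimated correlation), mt-Nd2 from 342.0 to 796.9 CPM. Among globins, adult Hbb-bs fell from 1376 to 588.6 CPM (log2 -1.23, adjusted p = 0.000193), Hbb-bt stood at 492 and 360.3 CPM (log2 -0.45, adjusted p = 0.109), and embryonic Hbb-y rose from 15.2 to 95.7 CPM (log2 2.65, adjusted p = 2.33e-07).

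In EXOSC10 total liver p53 targets and liver cell genes rose, and genes of red cells, cell division and B cells fell. Cdkn1a rose from 6.67 to 111 CPM (log2 4.09 ± 0.10, adjusted p = 2.26e-10), Eda2r from 0.291 to 13.0 CPM (log2 5.16 ± 0.26) and Hamp from 3.38 to 48.3 CPM (log2 3.96 ± 0.23). Ighm fell from 6.53 to 0.327 CPM (log2 -4.30 ± 0.23). Over 3 WT and 3 KO samples, 16771 genes were tested, and 5262 rose and 5202 fell, 1374 and 908 of them by at least 2-fold. Adjusted within this comparison, 25 lists were called. Splits that mix both genotypes gave 0 genes and 16 to 21 lists, which cannot measure chance. Of 30 p53 targets 25 rose and 2 fell (median 0.81, adjusted p = 3.56e-07, or 0.457 with an estimated correlation), with the same counts over the list alone, such as Zmat3 (13.4 to 76.7 CPM, log2 2.52 ± 0.07). All 18 hepatocyte genes rose (median 0.82, adjusted p = 6.59e-06, or 0.571 with an estimated correlation), Hnf4a from 177.5 to 312.9 CPM. Of 12 megakaryocyte genes 11 rose (median 0.47, adjusted p = 0.00413, or 0.602 with an estimated correlation), Vwf from 125.1 to 212.2 CPM. All 5 mast cell and basophil genes fell (median -1.08, adjusted p = 0.0136, or 0.484 with an estimated correlation), Cpa3 from 3.32 to 1.21 CPM. Endothelial genes rose in 10 of 12 cases (median 0.38, adjusted p = 0.0163, or 0.602 with an estimated correlation), as did stellate and mesenchymal genes (median 0.85, adjusted p = 0.00811, or 0.602 with an estimated correlation), such as Reln (718.3 to 1814 CPM). All 7 lymphoid genes fell (median -4.81, or -4.32 with bounds for genes at 0; adjusted p = 0.000154, or 0.328 with an estimated correlation), and Rag1 stood at 4.46 and 0.0145 CPM. Of 18 macrophage genes 13 fell and 3 rose (median -1.23, adjusted p = 0.00678, or 0.607 with an estimated correlation), Csf1r from 113.3 to 27.4 CPM.

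The red cell lists of EXOSC10 total liver fell almost whole. Membrane genes fell in 21 of 21 cases (median -1.19, adjusted p = 5.86e-09, or 0.571 with an estimated correlation), Rhd from 406.7 to 127.9 CPM (log2 -1.67 ± 0.09). Heme and iron genes fell in 19 of 20 cases (median -1.03, adjusted p = 3.43e-07, or 0.571 with an estimated correlation), Slc25a38 from 116.9 to 46.5 CPM. Of 16 erythroid transcription factors 15 fell (median -0.98, adjusted p = 1.72e-06, or 0.571 with an estimated correlation), among them the erythropoietin receptor gene Epor (176.5 to 68.4 CPM, log2 -1.36 ± 0.08). Terminal maturation genes fell in 17 of 18 cases (median -0.82, adjusted p = 1.11e-05, or 0.571 with an estimated correlation), Fbxo7 from 86.0 to 42.6 CPM. All but 1 of 20 S phase genes (median -1.004, adjusted p = 3.17e-09, or 0.567 with an estimated correlation) and all 20 G2 and mitosis genes (median -0.82, adjusted p = 3.3e-09, or 0.538 with an estimated correlation) fell, such as Cdc6 (130.6 to 56.7 CPM) and Nusap1 (170.0 to 70.4 CPM). DNA repair genes fell in 15 of 19 cases (median -0.63, adjusted p = 5.78e-05, or 0.563 with an estimated correlation), Brca2 from 131.4 to 75.7 CPM. Of 77 ribosomal protein genes 62 fell (median -0.36, adjusted p = 2.18e-09, or 0.484 with an estimated correlation), Rps7 from 143.2 to 98.5 CPM. The exosome and its cofactors fell in 14 of 24 cases and rose in 2 (median -0.24, adjusted p = 0.0198, or 0.571 with an estimated correlation), such as the helicase gene Mtrex (101.9 to 78.3 CPM, log2 -0.38 ± 0.06). Mitochondrial genome genes rose in 16 of 19 cases (median 1.33, adjusted p = 4.35e-05, or 0.571 with an estimated correlation), mt-Nd1 from 1196 to 3304 CPM. Of 877 lncRNAs 320 rose and 117 fell, 294 and 110 over the list alone (median 0.31, adjusted p = 0.00519, or 0.571 with an estimated correlation), such as Mirg (79.0 to 233.6 CPM), but coding genes matched for level had a median of 0.27 as well, 86.6% of that of the lncRNAs. The 289 divergent lncRNAs were not called as a list (71 rose and 40 fell, adjusted p = 0.235). MicroRNA hosts and precursors rose in 37 of 52 cases and fell in 4 (median 1.29, adjusted p = 5.53e-07, or 0.525 with an estimated correlation), such as Mir127 (1.34 to 3.98 CPM). Adult Hbb-bs fell from 523.6 to 224.3 CPM (log2 -1.22, adjusted p = 4.63e-05), while embryonic Hbb-y rose from 41.0 to 162.7 CPM (log2 1.96, adjusted p = 1.13e-05) and Hbb-bh1 fell from 3.37 to 2.12 CPM (log2 -0.61, adjusted p = 0.0274).

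**Figure D3:**
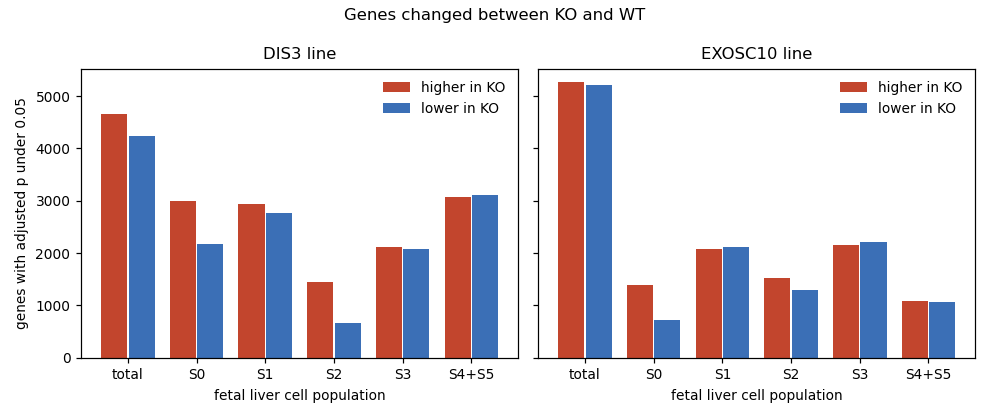
Genes that rose and fell in each comparison; the largest numbers were 5262 and 5202 in EXOSC10 total liver, and the smallest total was 2118 in DIS3 S2.

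In DIS3 S0, the fraction with progenitors, non-coding RNAs and p53 targets rose, and myeloid, lymphoid and histone genes fell. Zmat3, an RNA-binding p53 target, rose from 12.2 to 371.1 CPM (log2 4.93 ± 0.12, adjusted p = 9.31e-09) and Cdkn1a from 11.6 to 219 CPM (log2 4.24). Ahnak2 stood at 0.0283 and 14.9 CPM, and Zfp750, a regulator of skin cells, rose by at least 102-fold. Over 2 WT and 2 KO samples, 16616 genes were tested, and 2991 rose and 2164 fell, 1973 and 748 by at least 2-fold. Without WT replicate 2, 3254 genes were called. Of 506 divergent lncRNAs 351 rose and 1 fell, 390 and 3 over the list alone (median 2.37, adjusted p = 3.51e-36, or 0.319 with an estimated correlation), such as 4632427E13Rik (56.3 to 384.9 CPM, log2 2.77 ± 0.11). Of 1289 lncRNAs 681 rose and 26 fell (median 1.66, adjusted p = 1.41e-23, or 0.484 with an estimated correlation). Known nuclear lncRNAs rose in 8 of 11 cases (median 0.82, adjusted p = 0.0128, or 0.571 with an estimated correlation), Kcnq1ot1 from 959.4 to 2402 CPM (log2 1.32 ± 0.11) and Pvt1 from 8.38 to 77.5 CPM. Among 30 p53 targets 25 rose and 1 fell (median 2.39, adjusted p = 1.5e-10, or 0.563 with an estimated correlation). Of 21 red cell membrane genes 15 rose and 1 fell, 16 and 1 over the list alone (median 1.18, adjusted p = 6.31e-05, or 0.571 with an estimated correlation), Slc4a1 from 15.5 to 85.8 CPM. Granulocyte genes fell in 11 of 12 cases (median -2.31, adjusted p = 4.86e-08, or 0.495 with an estimated correlation), Elane from 61.0 to 2.38 CPM (log2 -4.76 ± 0.18). Of 11 macrophage genes 8 fell, 10 over the list alone (median -2.84, adjusted p = 2.16e-07, or 0.498 with an estimated correlation), Csf1r from 145.9 to 12.8 CPM, and so did 10 of 10 lymphoid genes (median -3.48, adjusted p = 7.42e-07, or 0.525 with an estimated correlation), Ebf1 from 26.8 to 0.504 CPM. Histone genes fell in 39 of 59 cases and rose in 2 (median -0.68, adjusted p = 1.71e-09, or 0.484 with an estimated correlation), although Hist2h2be, whose RNA can carry a poly(A) tail, rose from 11.7 to 48.4 CPM. G2 and mitosis genes fell in 16 of 20 cases, 19 over the list alone (median -0.52, adjusted p = 3.13e-06, or 0.571 with an estimated correlation), Aurkb from 86.7 to 53.1 CPM. Y-linked Ddx3y stood at 43.1 and 0.0560 CPM.

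In DIS3 S1, early erythroid cells, p53 targets and divergent lncRNAs rose while progenitor and granulocyte genes fell. Cdkn1a rose from 1.96 to 217 CPM (log2 6.74 ± 0.12, adjusted p = 2.25e-11). Ddit4, a stress gene that restrains growth signals, rose from 2.22 to 36.8 CPM (log2 4.01 ± 0.14), and the cartilage matrix gene Matn1 by at least 90-fold. Aqp1 fell from 175.4 to 13.3 CPM (log2 -3.69 ± 0.09) and the stem cell factor receptor gene Kit from 280.1 to 110.5 CPM (log2 -1.34 ± 0.06). With 2 WT and 2 KO samples, 14222 genes were tested, and 2936 rose and 2761 fell, 1275 and 877 by at least 2-fold. A single fit of all sorted samples of the line called 3768. Of 30 p53 targets 26 rose and 2 fell (median 1.94, adjusted p = 2.47e-13, or 0.309 with an estimated correlation). Of 383 divergent lncRNAs 285 rose and 6 fell, 296 and 8 over the list alone (median 1.97, adjusted p = 8.84e-30, or 0.237 with an estimated correlation), among them AI480526 (17.2 to 82.3 CPM, log2 2.29 ± 0.08). Of all 924 lncRNAs 500 rose and 49 fell (median 1.17, adjusted p = 9.08e-15, or 0.233 with an estimated correlation). All 12 granulocyte genes fell (median -4.32, adjusted p = 0.000414, then 0.602). Mpo fell from 386.6 to 9.07 CPM, with uneven WT samples (mean 321.8, SD 242.6 CPM in the WT series). Stem and progenitor genes fell in 10 of 15 cases and rose in 1 (median -0.96, adjusted p = 0.0031, then 0.571), Gfi1 from 11.5 to 0.842 CPM. Macrophage genes fell in 6 of 8 cases (median -3.94, or -3.49 with bounds; adjusted p = 0.00409, or 0.571 with an estimated correlation), Csf1r from 4.99 to 0.186 CPM. DNA repair genes fell in 15 of 19 cases, 17 over the list alone (median -0.38, adjusted p = 3.58e-05, then 0.567). Brca2 fell from 128.1 to 75.7 CPM. The heme and iron list rose in 11 of 20 cases and fell in 2 (median 0.27, adjusted p = 0.0395, or 0.658 with an estimated correlation), and Alas2 went from 15.3 to 57.7 CPM (log2 1.91 ± 0.09); this list was not called without KO replicate 1-3 (adjusted p = 0.0987) or WT replicate 1-3 (adjusted p = 0.135).

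In DIS3 S2, p53 targets and divergent lncRNAs rose and macrophage genes fell. Cdkn1a rose from 1.88 to 248 CPM (log2 7.01 ± 0.17, adjusted p = 9.76e-07), the lncRNA Trp53cor1 beside it by at least 135-fold and Zfp365, a gene linked to genome stability, by at least 158-fold. The red cell microRNA precursors Mir144 (0.484 to 33.9 CPM, log2 5.93 ± 0.43) and Mir451a (0.238 to 22.3 CPM, log2 6.39 ± 0.39) rose. Mpo fell from 105.3 to 11.96 CPM (log2 -3.19 ± 0.27) and Kit from 59.4 to 17.5 CPM (log2 -1.75 ± 0.14). Of 14035 genes tested over 2 WT and 2 KO samples, 1445 rose and 673 fell, 1073 and 352 by at least 2-fold. The 2118 calls moved to 872 without WT replicate 1-3, 1227 without WT replicate 2, 5898 without KO replicate 1-3 and 4455 without KO replicate 2, to 3392 with the replicate number as a block and to 4287 in a single fit of the sorted samples, where 41.7% of the calls were higher, against 68.2% here. Of 30 p53 targets 25 rose and none fell, 26 over the list alone (median 2.13, adjusted p = 9.17e-17, or 0.309 with an estimated correlation). Of 355 divergent lncRNAs 203 rose and 1 fell, 252 and 2 over the list alone (median 1.78, adjusted p = 3.51e-36, or 0.233 with an estimated correlation), such as Gm37305 (4.67 to 42.5 CPM, log2 3.18 ± 0.15). Of 882 lncRNAs 363 rose and 6 fell (median 1.17, adjusted p = 1.11e-23, or 0.309 with an estimated correlation). MicroRNA hosts and precursors rose in 5 of 25 cases (median 0.41, adjusted p = 0.01, or 0.571 with an estimated correlation). Of 15 macrophage genes 11 fell, 14 over the list alone (median -5.05, or -4.10 with bounds; adjusted p = 3.97e-12, or 0.546 with an estimated correlation), Csf1r from 7.09 to 0.173 CPM. Histone genes fell in 11 of 59 cases and rose in 1 (median -0.39, adjusted p = 5.04e-05, or 0.571 with an estimated correlation), Hist1h4d from 132.5 to 71.1 CPM.

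In DIS3 S3, p53 targets, ribosomal genes and lncRNAs rose, and genes of replication and mitosis fell. Cdkn1a rose from 3.18 to 308 CPM (log2 6.59 ± 0.15, adjusted p = 5.6e-11). Neat1, the lncRNA of paraspeckles, rose from 182.8 to 774.8 CPM (log2 2.08 ± 0.09). Aqp1 fell from 195.9 to 8.497 CPM (log2 -4.52 ± 0.11). Over 2 WT and 2 KO samples, 13052 genes were tested, and 2122 rose and 2070 fell, 901 and 310 by at least 2-fold. Without KO replicate 1-3, 2742 genes were called. Of 26 p53 targets 23 rose and 1 fell, 24 and 1 over the list alone (median 1.46, adjusted p = 1.41e-13, or 0.498 with an estimated correlation). Ribosome biogenesis genes rose in 16 of 30 cases, 18 over the list alone (median 0.30, adjusted p = 4.55e-05, or 0.484 with an estimated correlation), Gnl3 from 28.6 to 40.1 CPM. Ribosomal protein genes rose in 35 of 78 cases (median 0.25, adjusted p = 4.17e-05, or 0.571 with an estimated correlation), Rps28 from 8.58 to 16.8 CPM (log2 0.96 ± 0.14). Of 283 divergent lncRNAs 130 rose and 10 fell, 143 and 12 over the list alone (median 0.90, adjusted p = 1.53e-13, or 0.237 with an estimated correlation), 4632427E13Rik from 65.3 to 165.1 CPM. Of 739 lncRNAs 256 rose and 40 fell (median 0.41, adjusted p = 5.04e-07, or 0.309 with an estimated correlation). Histone genes fell in 49 of 60 cases and rose in 1 (median -0.76, adjusted p = 8.04e-13, or 0.571 with an estimated correlation), Hist1h2bn from 92.0 to 30.7 CPM. G2 and mitosis genes fell in 19 of 20 cases (median -0.52, adjusted p = 9.75e-08, or 0.567 with an estimated correlation), Kif11 from 491.2 to 297.6 CPM, and S phase genes in 15 of 20 (median -0.39, adjusted p = 1.74e-05, or 0.525 with an estimated correlation), Pcna from 469.1 to 319.9 CPM. DNA repair genes fell in 16 of 19 cases (median -0.43, adjusted p = 3.98e-05, or 0.571 with an estimated correlation), and macrophage genes fell in 11 of 14 and rose in 1 (median -2.38, adjusted p = 6.13e-05, or 0.571 with an estimated correlation), Cd5l from 3.48 to 0.105 CPM.

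In DIS3 S4+S5, the latest fraction, lncRNAs, microRNA precursors and p53 targets rose and macrophage, interferon and histone genes fell. Cdkn1a rose from 15.02 to 1321 CPM (log2 6.45 ± 0.17, adjusted p = 2.76e-15). Mir144 rose from 1.84 to 298.4 CPM (log2 7.37 ± 0.23) and Mir451a from 2.69 to 292.3 CPM (log2 6.81 ± 0.23), and the abundant nuclear lncRNA Malat1 from 11160 to 52740 CPM (log2 2.24 ± 0.12). Vcam1, an adhesion gene of the macrophages around which red cells mature, fell by at least 118-fold. With 2 WT and 2 KO samples, 13120 genes were tested, and 3072 rose and 3108 fell, 1924 and 2149 by at least 2-fold. In a single fit of the sorted samples 8240 were called, 35% of them higher. Of 30 p53 targets 26 rose and 2 fell (median 2.97, adjusted p = 3.04e-11, or 0.309 with an estimated correlation), Sesn2 from 16.8 to 315.3 CPM (log2 4.24 ± 0.17). Of 266 divergent lncRNAs 205 rose and 6 fell, 211 and 6 over the list alone (median 2.39, adjusted p = 3.06e-24, or 0.309 with an estimated correlation), such as Gm20633 (4.19 to 65.1 CPM). Of all 690 lncRNAs 410 rose and 43 fell (median 1.69, adjusted p = 1.77e-17, or 0.309 with an estimated correlation). MicroRNA hosts and precursors rose in 10 of 17 cases and fell in 1 (median 1.24, adjusted p = 0.000641, or 0.571 with an estimated correlation). Ribosomal protein genes rose in 45 of 76 cases, 48 over the list alone (median 0.58, adjusted p = 8.16e-07, or 0.571 with an estimated correlation), Rps4x from 96.4 to 211.6 CPM, while ribosome biogenesis genes fell in 18 of 30 cases and rose in 2 (median -0.75, adjusted p = 0.0016, or 0.571 with an estimated correlation), Heatr1 from 41.6 to 18.7 CPM. Macrophage genes fell in 15 of 16 cases (median -3.39, adjusted p = 4.73e-06, or 0.571 with an estimated correlation), Lyz2 from 642.7 to 42.7 CPM. Interferon-stimulated genes fell in 18 of 26 cases and rose in 1 (median -1.38, adjusted p = 4.26e-05, or 0.571 with an estimated correlation), Rsad2 from 502.3 to 178.5 CPM. Histone genes fell in 47 of 57 cases and rose in 1 (median -0.87, adjusted p = 7.29e-07, or 0.571 with an estimated correlation), Hist1h1c from 999.6 to 421.8 CPM. Adult Hbb-bs fell from 4029 to 1918 CPM (log2 -1.07, adjusted p = 3.57e-06), and embryonic Hbb-y stood at 1224 and 1362 CPM (log2 0.16, adjusted p = 0.389).

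In EXOSC10 S0, p53 targets and megakaryocyte genes rose and lymphoid genes fell, and smaller parts of the snoRNA and ribosome lists fell. Cdkn1a rose from 9.04 to 188 CPM (log2 4.41 ± 0.17, adjusted p = 9.78e-06) and Zmat3 from 11.5 to 299.2 CPM (log2 4.70 ± 0.15). Ano3, a gene of the anoctamin family of membrane proteins, rose by at least 323-fold. Ebf1, a factor that sets the B cell fate, fell from 32.2 to 0.577 CPM (log2 -5.87 ± 0.35), and Rpph1, the RNA of ribonuclease P, from 3865 to 1905 CPM (log2 -1.02 ± 0.11). Of 15754 genes tested over 2 WT and 2 KO samples, 1393 rose and 729 fell, 909 and 184 by at least 2-fold. The 2122 calls moved to 793 without WT replicate 2-3, 4471 without KO replicate 1, 3974 with exchanged replicate numbers as a block and 3211 without the expression filter. Camera called 22 lists here, while fry called 3. Of 30 p53 targets 25 rose and none fell, 27 over the list alone (median 2.18, adjusted p = 4.32e-18, or 0.538 with an estimated correlation). Megakaryocyte genes rose in 6 of 12 cases, 7 over the list alone (median 1.13, adjusted p = 0.000155, or 0.571 with an estimated correlation), Ppbp from 4.05 to 21.1 CPM. Lymphoid genes fell in 9 of 10 cases, 10 over the list alone (median -4.29, adjusted p = 6.77e-11, or 0.319 with an estimated correlation), Pax5 from 38.6 to 1.30 CPM. Other stable small RNAs fell in 4 of 7 cases, and over the list alone 6 fell and 1 rose (median -1.02, adjusted p = 0.00422, or 0.571 with an estimated correlation). Of 127 snoRNAs and scaRNAs 15 fell and none rose (median -0.55, adjusted p = 8.02e-08, or 0.571 with an estimated correlation), such as Snord17 (78.0 to 11.8 CPM, log2 -2.71 ± 0.36). Ribosome biogenesis genes fell in 15 of 30 cases, 24 over the list alone (median -0.44, adjusted p = 9.75e-08, or 0.579 with an estimated correlation), the nucleolin gene Ncl from 863.6 to 546.6 CPM, and ribosomal protein genes in 17 of 77 (median -0.32, adjusted p = 3.5e-08, or 0.602 with an estimated correlation), Rpl39 from 103.4 to 53.9 CPM. Histone genes fell in 25 of 58 cases and rose in 2 (median -0.56, adjusted p = 1.38e-08, or 0.571 with an estimated correlation), Hist1h2be from 118.4 to 62.7 CPM. Hepatocyte genes rose in 11 of 14 cases (median 4.38, adjusted p = 0.0018, or 0.645 with an estimated correlation), Fgb from 0.197 to 8.17 CPM. KO replicate 2-3 stood apart, with Alb at 393 CPM against 15.9 CPM in KO replicate 1 and Hbb-bs at 15.1 against 1.62 CPM.

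In EXOSC10 S1, p53 targets, stress genes and histone genes rose, and small nuclear RNAs, mitochondrial RNAs and granulocyte genes fell. Cdkn1a rose from 1.80 to 128 CPM (log2 6.23 ± 0.16, adjusted p = 8.31e-18), Matn1 by at least 116-fold and Ddit4 from 1.89 to 27.0 CPM (log2 3.98 ± 0.22). The stem cell surface gene Prom1 fell by at least 55.4-fold and the connexin gene Gjb2 from 9.32 to 0.0406 CPM. Over 2 WT and 2 KO samples, 13676 genes were tested, and 2085 rose and 2119 fell, 492 and 918 by at least 2-fold. Without WT replicate 1 the 4204 calls became 2673, and in a single fit of the sorted samples 2766. Among 29 p53 targets 26 rose and 1 fell (median 1.39, adjusted p = 9.41e-16, or 0.309 with an estimated correlation). Integrated stress response genes rose in 12 of 18 cases (median 0.47, adjusted p = 6.24e-05, or 0.484 with an estimated correlation), Mthfd2 from 65.0 to 158.3 CPM. Histone genes rose in 33 of 59 cases and fell in 1, 36 and 2 over the list alone (median 0.43, adjusted p = 3.72e-06, or 0.498 with an estimated correlation), Hist1h3e from 186.1 to 517.9 CPM (log2 1.48 ± 0.10). Ribosome biogenesis genes rose in 15 of 30 cases (median 0.23, adjusted p = 0.000992, or 0.571 with an estimated correlation), Nhp2 from 34.1 to 53.2 CPM, and ribosomal protein genes rose in 29 of 78 and fell in 3 (median 0.16, adjusted p = 0.00328, or 0.602 with an estimated correlation). Of 26 spliceosomal snRNAs 12 fell and none rose (median -1.09, adjusted p = 3.98e-05, or 0.538 with an estimated correlation), such as Gm23971 (73.5 to 9.77 CPM, log2 -3.06 ± 0.19). SnoRNAs and scaRNAs fell in 19 of 132 cases and rose in 3 (median -0.40, adjusted p = 4.73e-06, or 0.571 with an estimated correlation). Mitochondrial genome genes fell in 9 of 16 cases (median -0.71, adjusted p = 0.000684, or 0.602 with an estimated correlation), mt-Nd4 from 80.4 to 19.1 CPM. All 12 granulocyte genes fell (median -3.55, adjusted p = 4.05e-06, or 0.571 with an estimated correlation), Mpo from 270.3 to 5.47 CPM. Lymphoid genes fell in 7 of 8 cases (median -7.35, or -4.65 with bounds; adjusted p = 2.78e-06, or 0.571 with an estimated correlation), Rag1 by at least 41.3-fold, and macrophage genes in 7 of 9 (median -3.98, or -3.21 with bounds; adjusted p = 6.24e-05, or 0.571 with an estimated correlation), Csf1r from 7.44 to 0.158 CPM.

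In EXOSC10 S2, p53 targets and genes of stress, heme and late maturation rose, and macrophage and mast cell genes fell. Cdkn1a rose from 3.39 to 154 CPM (log2 5.60 ± 0.16, adjusted p = 1.32e-06), Sesn2, a stress gene regulated by p53, from 14.6 to 46.6 CPM (log2 1.68 ± 0.11) and Alas2 from 70.7 to 246.6 CPM (log2 1.81 ± 0.12). Aqp1 fell from 288.0 to 20.8 CPM (log2 -3.80 ± 0.10), the complement gene C1qb by at least 36.5-fold and Kit from 73.4 to 19.4 CPM (log2 -1.90 ± 0.14). With 2 WT and 2 KO samples, 13115 genes were tested, and 1517 rose and 1293 fell, 404 and 452 by at least 2-fold. Without WT replicate 2-3 the 2810 calls became 1647. Of 29 p53 targets 25 rose and none fell, 26 over the list alone (median 1.24, adjusted p = 8.23e-15, or 0.538 with an estimated correlation). Integrated stress response genes rose in 13 of 18 cases, and 14 rose and 1 fell over the list alone (median 0.69, adjusted p = 3.56e-07, or 0.563 with an estimated correlation). Heme and iron genes rose in 11 of 20 cases (median 0.28, adjusted p = 0.000245, or 0.484 with an estimated correlation), Slc25a37 from 1066 to 2271 CPM. Terminal maturation genes rose in 10 of 18 cases and fell in 2 (median 0.43, adjusted p = 0.00856, or 0.602 with an estimated correlation), Ube2o from 64.0 to 141.0 CPM. Of 15 macrophage genes 12 fell (median -3.63, or -3.49 with bounds; adjusted p = 4.54e-09, or 0.319 with an estimated correlation), Csf1r from 14.3 to 1.10 CPM, and so did 4 of 5 mast cell and basophil genes, or 5 of 5 over the list alone (median -1.62, adjusted p = 0.00485, or 0.579 with an estimated correlation), Ms4a2 from 7.44 to 1.98 CPM. Stem and progenitor genes fell in 6 of 14 cases and rose in 1 (median -0.70, adjusted p = 0.00449, or 0.571 with an estimated correlation), Gata2 from 26.9 to 7.50 CPM. Hepatocyte genes rose in 13 of 15 cases (median 2.93, adjusted p = 1.02e-09, or 0.319 with an estimated correlation), Fga from 0.222 to 3.67 CPM.

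In EXOSC10 S3, p53 targets and ribosome biogenesis genes rose, and Aqp1, histone and cell cycle genes fell. Aqp1 (chromosome 6, plus strand, 55336432 to 55348555) fell from 236.6 to 8.08 CPM (log2 -4.89 ± 0.08, adjusted p = 5.93e-13), and the lipid transfer gene Stard10 from 16.9 to 0.656 CPM (log2 -4.67 ± 0.20). Cdkn1a (chromosome 17, plus strand, 29090976 to 29100727) rose from 3.49 to 141 CPM (log2 5.43 ± 0.10), Tmtc1, a mannosyltransferase gene, from 0.728 to 59.0 CPM (log2 6.36 ± 0.14) and Kcp, a regulator of BMP signals, from 0.18 to 25.2 CPM (log2 6.79 ± 0.26). Of 12774 genes tested over 2 WT and 2 KO samples, 2150 rose and 2202 fell, 538 and 456 by at least 2-fold. The DESeq2 Wald test called 2886 genes and a single fit of the sorted samples 2369. Of 27 p53 targets 24 rose and 1 fell (median 1.59, adjusted p = 2.9e-12, or 0.309 with an estimated correlation), such as Zmat3 (2.75 to 38.4 CPM). Ribosome biogenesis genes rose in 29 of 30 cases and in 30 over the list alone (median 0.48, adjusted p = 1.02e-09, or 0.319 with an estimated correlation), Gnl3 from 27.1 to 46.2 CPM, and ribosomal protein genes rose in 36 of 78 and fell in 4 (median 0.20, adjusted p = 0.000641, or 0.571 with an estimated correlation), Rpl11 from 41.9 to 71.7 CPM. Histone genes fell in 44 of 60 cases (median -0.63, adjusted p = 2.55e-12, or 0.484 with an estimated correlation), Hist1h2bb from 223.5 to 87.5 CPM. G2 and mitosis genes fell in 17 of 20 cases (median -0.41, adjusted p = 1.91e-06, or 0.571 with an estimated correlation), Ccnb2 from 207.7 to 133.6 CPM, and S phase genes in 14 of 20 (median -0.31, adjusted p = 4.01e-05, or 0.567 with an estimated correlation), Mcm7 from 563.5 to 396.8 CPM. Interferon-stimulated genes fell in 8 of 16 cases and rose in 1 (median -0.70, adjusted p = 0.00131, or 0.507 with an estimated correlation), Cmpk2 from 21.6 to 4.03 CPM. Macrophage genes fell in 12 of 15 cases and rose in 1 (median -2.51, adjusted p = 2.4e-05, or 0.563 with an estimated correlation), Cd5l from 6.60 to 0.370 CPM.

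In EXOSC10 S4+S5, p53 targets and ribosomal protein genes rose, and lymphoid, macrophage and mitotic genes fell. Cdkn1a rose from 9.43 to 504 CPM (log2 5.74 ± 0.14, adjusted p = 0.000102), Mdm2, the ubiquitin ligase that limits p53, from 45.3 to 248.5 CPM (log2 2.46 ± 0.10) and Got1l1, an aminotransferase-like gene, by at least 220-fold. Rag1 stood at 6.80 and 0.0202 CPM. Over 2 WT and 2 KO samples, 14146 genes were tested, and 1080 rose and 1064 fell, 652 and 496 by at least 2-fold. The 2144 calls became 1290 without WT replicate 1, 1277 without WT replicate 2-3, 7704 without KO replicate 1 and 7872 without KO replicate 2-3. KO replicate 1 stood apart, with counts in 14264 genes against 17441 and 17385 in the other KO libraries. Calls became 6521 in a single fit of the sorted samples (26.4% of them higher, with the median of all genes shifted by -0.229) and 3493 without the expression filter. Of 30 p53 targets 21 rose and none fell, and 22 rose and 1 fell over the list alone (median 2.13, adjusted p = 8.03e-14, or 0.309 with an estimated correlation). Ribosomal protein genes rose in 30 of 77 cases, 34 over the list alone (median 0.55, adjusted p = 3.17e-09, or 0.525 with an estimated correlation), Rps19 from 33.3 to 74.2 CPM (log2 1.16 ± 0.10). Of 16 macrophage genes 13 fell and 1 rose (median -2.21, adjusted p = 9.95e-07, or 0.567 with an estimated correlation); Cd5l fell from 34.4 to 1.58 CPM, while Hmox1, which breaks down heme, rose from 46.3 to 172.1 CPM (log2 1.90 ± 0.15). Lymphoid genes fell in 6 of 8 cases, 7 over the list alone (median -5.29, or -4.19 with bounds; adjusted p = 5.96e-05, or 0.484 with an estimated correlation). G2 and mitosis genes fell in 13 of 20 cases, 18 over the list alone (median -0.56, adjusted p = 1.79e-05, or 0.571 with an estimated correlation), Kif11 from 386.4 to 217.4 CPM. Interferon-stimulated genes fell in 8 of 26 cases, 11 over the list alone (median -1.005, adjusted p = 2.6e-05, or 0.536 with an estimated correlation), Irf9 from 51.1 to 24.9 CPM. Adult Hbb-bt fell from 815.8 to 415.8 CPM (log2 -0.97, adjusted p = 0.0225). The adult globins Hbb-bs (log2 -0.38, adjusted p = 0.281), Hba-a1 (log2 0.091, adjusted p = 0.795) and Hba-a2 (log2 1.70, adjusted p = 0.131) were not called. Embryonic Hbb-y rose from 89.4 to 291.4 CPM (log2 1.71, adjusted p = 0.0125).

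**Figure D4:**
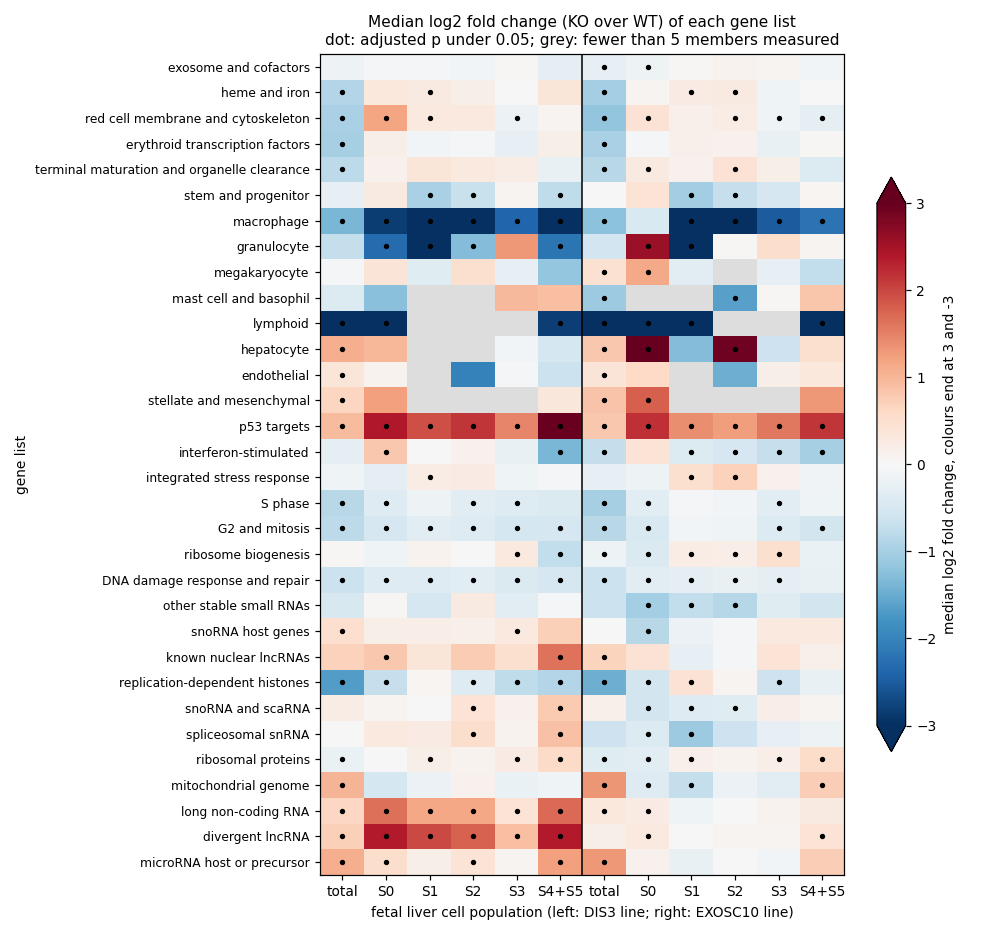
Median log2 value of every gene list in every comparison; 183 of 364 list tests were called, 81 upward and 102 downward.

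Many genes moved the same way in both lines, and others differed between them. Mir451a in total liver (log2 2.52 in DIS3 and -0.86 in EXOSC10, difference 3.39) and Mir144 in S4+S5 (7.37 and -0.16, difference 7.36) had the higher DIS3 effect. Xist, the RNA that silences an X chromosome, did so in S4+S5 (difference 3.20), where the DIS3 WT samples held Y-linked RNA beside Xist. The peptide transporter gene Slc15a2 had the lower DIS3 effect in S0 (-2.996 and 1.54, difference -4.55) and S4+S5 (-3.80 and 1.11, difference -4.89), Kcp did in S3 (0.33 and 6.79, difference -6.46), and histone Hist2h3c2 did in S1 (-0.41 and 1.18, difference -1.57). The divergent lncRNA 4632427E13Rik had the higher DIS3 effect in S1 (2.30 and 0.05, difference 2.26). The interaction test called 185 genes in total liver (105 with a higher and 80 with a lower DIS3 effect), 1253 in S0 (575 and 678), 592 in S1 (471 and 121), 311 in S2 (253 and 58), 191 in S3 (135 and 56) and 1045 in S4+S5 (523 and 522). These counts moved with single samples, to between 85 and 248 in total liver, 677 and 1695 in S0, 291 and 589 in S1, 62 and 2791 in S2, 84 and 181 in S3 and 205 and 2742 in S4+S5. In total liver 3677 genes rose in both lines (1364.5 expected if calls were unrelated), 3547 fell in both (1300.0 expected) and 48 went opposite ways (2665.7 expected). In S0 the numbers were 823 (216.7 expected), 424 (100.1 expected) and 136 (302.4 expected). The Pearson correlation of the effects was 0.856 in total liver, 0.498 in S0, 0.807 in S1, 0.680 in S2, 0.747 in S3 and 0.644 in S4+S5, over genes that are not independent replicates.

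Within a line, the effect of the KO also depended on the population. In the DIS3 line the glucose transporter gene Slc2a3 had log2 values of 0.37, 0.10, -0.06, 2.61 and 3.71 from S0 to S4+S5, and Csf2rb2, a chain of the interleukin 3 receptor, of -1.52, 0.48, 2.74, 5.30 and 2.34. In the EXOSC10 line the interleukin 4 receptor gene Il4ra had 0.32, 0.87, 2.33, 5.78 and 4.38, and Tmtc1 had 0.07, 3.96, 6.42, 6.36 and 8.07. The test across the 5 populations called 6062 of 17548 genes in the DIS3 line and 5147 of 17167 in the EXOSC10 line.

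The maturation index weighs S4+S5 against S0 genes of any cell type. It was lower in KO total liver and higher in KO S1 and S2, but no group was large enough to call it. In DIS3 total liver it was 5.75 ± 0.28 (SD, 4 WT) and 4.83 ± 0.17 (2 KO), a difference of -0.92 (exact p = 0.0667, the smallest possible), and in EXOSC10 total liver 4.47 ± 0.04 and 3.64 ± 0.08 (3 and 3), a difference of -0.83 (exact p = 0.1, the smallest possible). In sorted DIS3 cells the differences were 0.09 in S0 (exact p = 0.667), 0.83 in S1 (exact p = 0.333), 0.63 in S2 (exact p = 0.333), 0.01 in S3 (exact p = 1) and 0.09 in S4+S5 (exact p = 0.667). In sorted EXOSC10 cells they were 0.64 in S0 (exact p = 0.333), 0.74 in S1 (exact p = 0.333), 0.82 in S2 (exact p = 0.333), 0.16 in S3 (exact p = 0.333) and 0.18 in S4+S5 (exact p = 0.667). With 2 samples per group the exact p cannot fall below 0.333. With genes of the same line the differences turned to -0.474 in DIS3 S4+S5 and -0.83 in EXOSC10 S4+S5, and became 0.904 in DIS3 S0.

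**Figure D5:**
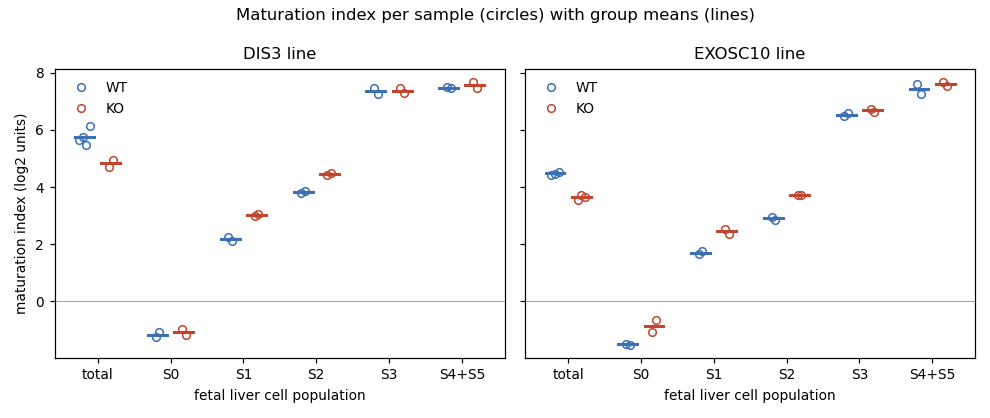
Maturation index per sample; the KO minus WT difference was -0.92 in DIS3 total liver and -0.83 in EXOSC10 total liver.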

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

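Of the tests in this part, those of joint scaling, of embryo sex and of cell shares and levels within cells as the cause of the total liver changes were chosen after the results were seen.

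By tests of interaction, the KO effect differed between lines and between populations for many genes. Between lines it differed for 185 genes in total liver, 1253 in S0, 592 in S1, 311 in S2, 191 in S3 and 1045 in S4+S5. Leaving out single samples moved these counts to as few as 85 (without EXOSC10 WT replicate 3-4), 677 (EXOSC10 WT replicate 2-3), 291 (DIS3 WT replicate 1-3), 62 (DIS3 WT replicate 1-3), 84 (EXOSC10 KO replicate 2-3) and 205 (DIS3 KO replicate 1-3), in that order. Across the sorted populations it differed for 6062 genes in the DIS3 line and 5147 in the EXOSC10 line. The genes with the smallest p per direction were, as DIS3 minus EXOSC10 log2 effects, 4930503L19Rik (1.71) and Pou2f2 (-2.01) in total liver, ENSMUSG00000097769 (3.08) and Slc15a2 (-4.55) in S0, and ENSMUSG00000097769 (2.15) and Gm24270 (-5.48) in S1. In the later fractions they were Mir142hg (4.07) and Slc15a2 (-4.46) in S2, Xist (1.78) and Slc15a2 (-3.78) in S3, and Gm29358 (4.61) and Slc15a2 (-4.89) in S4+S5.

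Long non-coding RNAs rose as a group in all 6 DIS3 comparisons, with medians from 0.41 in S3 to 1.69 in S4+S5. None of these lists was called with an estimated correlation (adjusted p 0.233 to 0.484), a test with little power at these sample numbers. Low expression is argued against, since coding genes matched for level reached at most 38.8% of the lncRNA median in any of the 6. Reads of an overlapping gene on either strand are argued against as well: lncRNAs with no overlapping gene kept at least 115.5% of the median of all. Scaling is argued against: other factors within a comparison moved the median of all genes by at most 0.02, and in the single fit of all sorted samples, which moved it by up to -0.223 (S4+S5), lncRNAs kept at least 75.8% of their median (S3, 0.416 to 0.315). Loss of DIS3 may therefore raise or stabilise such RNAs, a hypothesis from the same data, while embryo sex, which differs between the DIS3 groups, and any batch of the WT embryos stay open.

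In DIS3 WT total liver, replicate 3 stood apart from replicates 1, 2 and 4 by Dixon's test. It had Xist at 1270 CPM (others 0.164 to 1.32), Ddx3y at 0.0791 CPM (others 42.6 to 50.3) and Uty at 0.158 CPM. Chance gives such a result in about 1 in 20 groups per value, so 1 or more among 24 tested is no rarity. All 3 flagged, however, were X- or Y-linked. Ddx3y reached at most 0.112 CPM in any DIS3 KO sample, so female KO embryos and mostly male WT embryos in total liver are a candidate explanation of the Y-linked falls. In the sorted WT samples Xist (244 to 1120 CPM) and Ddx3y (30.3 to 43.6 CPM) occur side by side, which a mixture of both sexes could give. Sex as the source of the autosomal calls in DIS3 total liver is argued against: of autosomal genes called between WT replicates 1, 2 and 4 and 1 KO sample, 94.8% and 98.6% kept their sign between WT replicate 3 and the other KO sample, against 56.2% and 55.9% of autosomal genes with an unadjusted p of at least 0.5. Smaller effects of sex on single genes stay open, also in the sorted cells, where sex differs between WT and KO.

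In total liver of both lines erythroid lists fell while hepatocyte, endothelial and mesenchymal lists rose, although none of these calls held with an estimated correlation (adjusted p 0.319 to 0.602). A lower share of erythroid cells stays open as the cause of this pattern. It would not lower lymphoid genes (median -4.81 or lower in both lines, -4.32 with bounds for genes at 0), which lie outside the pattern. Under scaling within each comparison, lower levels within sorted cells as the whole cause are argued against for 3 lists. Their lowest medians in the 10 sorted comparisons were -0.296 (red cell membrane, -0.97 and -1.19 in total liver), -0.124 (heme and iron, -0.88 and -1.03) and -0.247 (erythroid transcription factors, -1.0 and -0.98). Lower levels stay open for terminal maturation genes (-0.406, against -0.79 and -0.82) and adult globins (-1.083 in DIS3 S4+S5, -0.795 in total liver). In EXOSC10 S4+S5 globins went both ways (-0.974 to 1.7, median -0.144, total liver -1.02). A loss of several blood cell types may underlie the rest, since macrophage genes fell too (-1.37 and -1.23), although megakaryocyte genes rose in the EXOSC10 line (0.47); no test here measures cell numbers.

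The 3 WT and 3 KO samples of EXOSC10 total liver allow 10 splits, too few for a share under 0.05. The real one gave 10464 genes and 25 lists. The others mix genotypes within groups, so their 0 genes and 16 to 21 lists cannot measure chance.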

How the results depend on the processing

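The tests chosen after the data were seen are every library as its own sample, the omission of Gm26917 and Gm42418 or of chromosomes X and Y, DIS3 total liver with only the WT sample without Y-linked counts, the block with exchanged replicate numbers, and the list tests without the first or second WT or KO sample; all others were fixed before.

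Of the counts of changed genes under another setting, 137 stayed within 1.5 times the value reported and 29 moved further; between lines 39 stayed and 36 moved, across populations 46 and 2, and in the WT series all 28 stayed. Of the values of named genes, 15194 kept direction and side of the threshold, 382 lost the call, 4 gained it and 4 changed sign. Other scaling factors within a comparison moved the median of all genes by at most 0.02, but the single fit of a line's sorted samples, which scales them jointly, moved it by -0.129 in DIS3 S2, -0.101 in DIS3 S3, -0.223 in DIS3 S4+S5 and -0.229 in EXOSC10 S4+S5.

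Without single samples the genes changed ran from 6675 to 8871 in DIS3 total liver (8899 with all), 3254 to 7324 in S0 (5155), 3886 to 5642 in S1 (5697), 872 to 5898 in S2 (2118), 2742 to 4049 in S3 (4192) and 4618 to 5758 in S4+S5 (6180). In the EXOSC10 line they ran from 9211 to 10115 in total liver (10464), 793 to 4471 in S0 (2122), 2673 to 3700 in S1 (4204), 1647 to 3775 in S2 (2810), 2919 to 3946 in S3 (4352) and 1277 to 7872 in S4+S5 (2144). The samples behind moves over 1.5 times were DIS3 WT replicate 2 in S0 (3254), all 4 in DIS3 S2 (872, 1227, 5898 and 4455), DIS3 KO replicate 1-3 in S3 (2742), EXOSC10 WT replicate 2-3 (793) and KO replicate 1 (4471) in S0, WT replicate 1 in S1 (2673), WT replicate 2-3 in S2 (1647) and all 4 in EXOSC10 S4+S5 (1290, 1277, 7704 and 7872). In the sorted groups this leaves 1 sample, assumed to vary like the others. Genes whose effect differs between lines ran from 85 to 248 in total liver, 677 to 1695 in S0, 291 to 589 in S1, 62 to 2791 in S2, 84 to 181 in S3 and 205 to 2742 in S4+S5. Samples that moved these counts over 1.5 times were, in total liver, DIS3 WT replicate 1 (109), EXOSC10 WT replicate 3-4 (85) and KO replicate 1 (90). In S0 they were DIS3 WT replicates 1-3 (770) and 2 (780), EXOSC10 WT replicate 2-3 (677) and KO replicate 2-3 (834); in S1, DIS3 WT replicate 1-3 (291) and KO replicate 2 (361). In S2 all 8 did: DIS3 WT replicates 1-3 (62) and 2 (117), DIS3 KO replicates 1-3 (2791) and 2 (503), EXOSC10 WT replicates 1 (153) and 2-3 (97), EXOSC10 KO replicates 1 (165) and 2-3 (104). In S3 they were DIS3 KO replicate 1-3 (97), EXOSC10 WT replicate 2-3 (88) and KO replicate 2-3 (84). In S4+S5 they were DIS3 WT replicate 2 (658) and KO replicate 1-3 (205), EXOSC10 WT replicates 1 (387) and 2-3 (417), and EXOSC10 KO replicates 1 (2081) and 2-3 (2742). The 120 divergent lncRNAs with a higher DIS3 effect in S0 became 84 to 149, a range chosen after the values were seen.

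The single fit of all sorted samples of a line gave 3768 changed genes in DIS3 S1, 4287 in DIS3 S2 (41.7% of them higher, 68.2% in the separate fit), 2766 in EXOSC10 S1, 2369 in EXOSC10 S3 and 6521 in EXOSC10 S4+S5 (26.4% higher). Without an expression filter EXOSC10 S0 gave 3211, EXOSC10 S4+S5 3493, and the test between lines 672 in total liver, 932 in S2, 468 in S3 and 1876 in S4+S5. The DESeq2 Wald test gave 2886 in EXOSC10 S3. With the only WT sample without Y-linked counts, DIS3 total liver gave 4992. With every library as its own sample DIS3 S2 gave 4297, EXOSC10 S0 5636, S2 4596 and S4+S5 5141, the test between lines 992, 3882, 1725, 1855, 1151 and 3752 from total liver to S4+S5, and the test across populations 9779 and 9421 in the DIS3 and EXOSC10 lines; near-identical libraries counted as replicates make the spread too small.

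No paired analysis was possible in total liver, because the summed replicate numbers are not shared between WT and KO. In sorted cells the replicate block gave 3392 in DIS3 S2, and with exchanged numbers it gave 3974 in EXOSC10 S0. WT and KO samples of equal number correlated at -0.19 to 0.33 in the DIS3 line and -0.24 to 0.09 in the EXOSC10 line over genes, which are not independent replicates. Populations of equal number within EXOSC10 WT correlated at 0.14 to 0.59 in all 10 pairs, so they may share embryos or a batch, which the tests over populations without a block ignore; with the block these called 5437 genes for the EXOSC10 KO effect (5147 without) and 14231 in EXOSC10 WT (14098 without).

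With the correlation estimated per list 0 of the 364 list tests were called, against 183 with the preset value; fry called 157 (124 shared), with 3 in EXOSC10 S0 against 22 by camera, and the other list settings called 174 to 199, with no list called in the opposite direction. The list test without the same replicate of both groups was not run, since it leaves 1 sample against 1. Over genes with an average log2 CPM of at least 3 the correlation between lines was 0.848 in S3 and 0.791 in S4+S5.

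The maturation index difference in total liver of the EXOSC10 line was -0.955 with 300 genes per direction, -0.931 without globin genes and -1.108 with genes of the same line. With 300 genes it was 0.581 in DIS3 S1, 0.365 in DIS3 S2, 0.327 in DIS3 S4+S5 and 0.692 in EXOSC10 S2. Without globin genes it was 0.684 in DIS3 S2 and 0.051 in EXOSC10 S3, and with genes of the same line 0.904 in DIS3 S0, 0.743 in DIS3 S2, -0.474 in DIS3 S4+S5, 0.001 in EXOSC10 S3 and -0.83 in EXOSC10 S4+S5, so its direction in S4+S5 depends on the genes chosen. The block for the index gives the same value and was not run.

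Signs changed for Rn7s2 in DIS3 S4+S5 (-0.691; without single samples -1.215 to 0.03, the latter without WT replicate 2) and in EXOSC10 S1 for Afp (-2.123; -3.102 to 0.235), Alb (-2.085; -3.077 to 0.452) and Apob (-2.228; -4.424 to 0.543), each with the positive value without WT replicate 1.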

Other observations

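All patterns in this part were chosen after the values were seen, and none of their tests was fixed before.

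LncRNAs were frequent among genes with a higher KO effect in the DIS3 line, although no test of enrichment was run. Among genes whose KO effect was higher in the DIS3 line by the interaction test, lncRNAs made up 224 of 575 in S0, 198 of 471 in S1, 111 of 253 in S2, 31 of 135 in S3, 95 of 523 in S4+S5 and 35 of 105 in total liver. Among those with a lower DIS3 effect they were 7 of 675, 3 of 121, 1 of 58, 4 of 56, 5 of 522 and 3 of 80 (only genes with a unique name were counted). Of all genes tested, lncRNAs were 7.75%, 6.52%, 5.75%, 5.66%, 6.07% and 6.46% in the same order. In S0, 120 of the 575 but 0 of the 675 were divergent lncRNAs. The median difference between lines was 1.21 for lncRNAs and -0.001 for other genes in S0, and 0.225 and 0.013 in total liver. Divergent transcripts may depend more on DIS3 than on EXOSC10 in these cells; the 120 became 84 to 149 without single samples, and the embryos of the DIS3 groups differ in sex. Other non-coding RNAs went the opposite way, such as Gm24270 (-5.48) and Gm23935 (-6.90) in S1.

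Aqp1 fell in all 12 comparisons, by log2 values from -1.53 in DIS3 S0 to -4.89 in EXOSC10 S3. Gm23935, an annotated microRNA, stood in EXOSC10 S0 at 12.5 and 5.05 CPM in WT and at 1320 and 538 CPM in KO, in S1 at 6.04 and 0.768 against 770 and 373 CPM, and in S4+S5 at 42.5 and 2.79 against 526 and 804 CPM. In EXOSC10 total liver it stood at 743 to 1030 CPM in WT and 789 to 1110 CPM in KO, and in DIS3 S0 at 32.3 and 7.35 CPM in WT and 8.14 and 35.9 CPM in KO. In the DIS3 line Gm23935 was higher in KO in S1 (11.9 and 11.5 against 28.5 and 20.2 CPM) and lower in KO in S4+S5 (50.3 and 76.4 against 3.59 and 15.3 CPM) and total liver (824 to 1260 against 589 and 599 CPM). No explanation of these levels was tested.

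Hepatocyte genes were detected in sorted EXOSC10 cells. Alb stood in S0 at 3.66 and 8.41 CPM in WT and 15.9 and 393 CPM in KO, and in S2 at 3.30 and 4.82 CPM in WT and 51.2 and 51.4 CPM in KO. Its levels overlapped in S1 (22.3 and 1.92 CPM in WT, 2.69 and 2.60 CPM in KO), S3 (6.58 and 36.1, and 36.4 and 8.19 CPM) and S4+S5 (11.2 and 26.4, and 12.3 and 36.9 CPM).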
